A study of Mus musculus with 292 samples.

How the data were processed

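Messenger RNA was measured by sequencing in 292 libraries from the cortex, striatum, hypothalamus and liver of wild-type C57BL/6J male mice aged 26 weeks. Per the labels, the cortex came from the right hemisphere, total RNA was extracted with a Qiagen miRNeasy kit, and libraries were made by Illumina's protocol. For each tissue the deposited data hold a table of raw counts per Ensembl gene and a table of FPKM values made by the authors (counts scaled by the length of the gene model and by the total of the library). Each FPKM value was checked against the counts and was proportional to the count over the library's total, with a constant per gene. The submitters' processing notes name STAR 2.7.3a, HTSeq 0.10.0 and the builds GRCm38 and mm10, with no order or role. The annotation release and the strand setting are not given in the sources used here. The tables hold 48795 gene identifiers, of which 48349 were matched to a symbol. Gene positions and shared exonic bases were taken from GENCODE release M21 on GRCm38, which may not be the release behind the counts.

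Libraries were grouped by tissue and by ZT as the labels give them, at 13 time points from 0 to 36 h, folded onto 8 ZT groups. The labels carry 79 mouse codes, 58 of them in 4 tissues, 19 in 3, 1 in 2 and 1 in 1. A code that differs from the others in form was kept as a mouse of its own. The same code marks the same animal, so tissues were paired by it. Replicate numbers pair nothing that the labels state, and a replicate block was run as another setting. The tissues, groups, tests, gene lists, the first set of other settings and the rule for named genes were fixed before the data were examined.

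Rhythms were tested on the counts with edgeR 4.0.16, in each tissue alone. Genes passed filterByExpr with the ZT group, and libraries were scaled by TMM. The quasi-likelihood test had 2 degrees of freedom, for the cosine and sine of ZT with a period of 24 h. A gene was called rhythmic at a Benjamini-Hochberg adjusted p under 0.05, and counted again at a fitted peak-to-trough ratio of 1.5-fold or more. The ratio is the fitted peak over the fitted trough of the cosine, and ± beside a log2 ratio is its standard error by the delta method. A fitted ratio is never negative and lies above 0 for noise too. CPM values of single libraries, of the thresholds and of the figures are counts scaled to the library total. Means over the libraries of a ZT group or a cycle, with their SD, are of counts scaled to the total times the TMM factor. The second cycle was compared with the first at ZT0, ZT3, ZT6, ZT9 and ZT12, with ZT as a factor. Rhythms were compared between tissues through the interaction of tissue with cosine and sine, in genes that passed the filter in both. The overlap of all 4 tissues was taken among genes tested in each.

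The 32 gene lists held 517 members, all matched to a symbol. They covered the clock and its output, immediate early genes, chaperones, cold-inducible genes, ER stress and glucocorticoid response. Metabolic lists covered cholesterol and fatty acid synthesis, bile acids, gluconeogenesis and glycogen, fatty acid oxidation, the urea cycle and amino acid breakdown, xenobiotic metabolism and liver genes under feeding and clock control. Others covered ribosomal proteins, oxidative phosphorylation, the cell cycle, interferon and acute phase, male-biased liver genes and hypothalamic neuropeptides. Markers covered striatal projection neurons, synapses, oligodendrocytes and their precursors, astrocytes, microglia, endothelial and mural cells, choroid plexus, pituitary, blood, hepatocytes and other liver cells. A list needed 3 measured members. The mean over members of centred log2 CPM (prior count 2) was fitted with the same cosine, and its p came from 100000 permutations of ZT over the libraries of the tissue, with no direction or peak time set. Member counts were tested by Fisher's exact test, one-sided. Benjamini-Hochberg adjustment ran over all 122 list and tissue combinations for each test. Some genes are on several lists, such as Per1 and Pdk4.

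The named genes were chosen by rule: the clock list in each tissue, and per tissue the 10 called genes with the largest ratio among those with a mean log2 CPM of at least 1. From every other list came the 4 called members with the smallest adjusted p, in the tissue where the list mean had the smallest p. The rule also took the 4 genes with the smallest p outside the clock list per pair of tissues, and the 3 with the smallest p between cycles per tissue. For the cycles the adjusted p was used, and genes tied in it were taken in alphabetical order. The rule further took the 10 genes called in all 4 tissues with the largest minimum ratio. Models without a symbol were skipped. A part of the named genes is described in the text. Some of the genes that the rule took are not reported here, and they stayed in every count and test.

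The other settings fixed at that time were DESeq2 size factors, DESeq2 1.42.0's likelihood ratio test, limma 3.58.1 on the deposited FPKM with a pseudocount of 0.1 or 1, no filter, ZT as a factor, the second cycle or the library's L code as a covariate, the replicate block, the first cycle alone, robust dispersion, and leaving out each time point and each replicate number. Pairs of tissues were also fitted with the mouse as a block, in mice with both tissues. Further settings were chosen after seeing the data: libraries that stood apart were left out, composition covariates were entered (the Gm42418 share, and in brain also the means of the striatal, oligodendrocyte and choroid plexus lists), and a replicate block was added to the cycle test. Libraries stood apart when Slc17a7 was under 50 CPM in cortex, Gabra6 over 100 CPM in striatum, Gh over 1000 CPM in hypothalamus, Gm42418 over 50% of the counts or the total under 20 M. These limits were set after marker levels and totals had been seen, and Gabra6 and Gh are themselves among the named genes. All libraries stayed in the main values.

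Chance was judged by 25 splits per tissue, the real one included, with ZT permuted over libraries, or the cycle permuted within ZT groups. For pairs of tissues 100 splits swapped the tissue names within mice, tested by limma. The methods were tested on simulated data, with 200 planted genes per fit at 1.25-fold, 1.5-fold or 2-fold. Of planted 2-fold rhythms 97.0% were found in cortex, 60.6% in striatum, 93.9% in hypothalamus and 93.9% in liver, and of planted 1.25-fold rhythms 52.2%, 5.97%, 50.7% and 53.7%. False calls numbered 10, 1, 6 and 7. The simulated genes were drawn independently, so these numbers leave out errors that many genes share, and a split of the real striatum libraries called 4464 genes. Of planted 2-fold differences in rhythm 75.8% were found between cortex and striatum. The 28 false calls there stood beside 7, 31 and 50 found at 1.25-fold, 1.5-fold and 2-fold, a larger share than the threshold of 0.05 allows. Of the planted list means 20 of 20 were found, and 0 of 20 unchanged ones (permutation test, unadjusted p under 0.05). They were planted in the cortex layout alone, with a cosine amplitude equal to the SD of the noise. No smaller size was tried, so this does not measure the power for small list rhythms or in striatum. The other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Totals per library ran from 11.7 to 50.01 M counts, and intervals for single libraries are Wilson 95% intervals. No library was left out, and reads were not used here, so mapping and transcript isoforms were not examined.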

Results

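Messenger RNA was sequenced from the cerebral cortex, striatum, hypothalamus and liver of wild-type male C57BL/6J mice aged 26 weeks. Mice were taken every 3 h over 36 h, which gave 13 time points that fold onto 8 groups of zeitgeber time (ZT, by convention the hours since lights-on). ZT0, ZT3, ZT6, ZT9 and ZT12 were sampled in both cycles, and ZT15, ZT18 and ZT21 in the first cycle. There were 78 cortex, 60 striatum, 77 hypothalamus and 77 liver libraries. A ZT group held 6 to 12 libraries in cortex, hypothalamus and liver. In striatum it held 2 at ZT15, 4 at ZT18, 6 at ZT21 and 8 to 11 at the other times. Total gene counts per library, in mega counts (M), ran from 28.3 to 40.5 M in cortex, from 11.7 to 43.4 M in striatum, from 29.2 to 50.01 M in hypothalamus and from 11.7 to 41.9 M in liver.

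Some libraries stood apart from the rest of their tissue in marker genes or depth. The cortex libraries ZT0 replicate 1 and ZT9 replicate 9 held 4.41 (3.8 to 5.12, Wilson 95% interval) and 12.7 (11.5 to 14) CPM (the count scaled to the library total) of Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, against 882 to 1300 CPM in the other 76 cortex libraries. The striatum library ZT21 replicate 3 held 874 CPM (864 to 885) of Gabra6, a GABA receptor subunit of cerebellar granule cells. The striatum library ZT3 replicate 5 had a total of 11.7 M. The hypothalamus libraries ZT0 replicate 9 and ZT9 replicate 9 held 29306 CPM (29253 to 29359) and 20929 CPM (20877 to 20981) of Gh, the growth hormone gene of the pituitary. In the liver library ZT18 replicate 4, which totalled 11.7 M, Gm42418 took 62.3% of the counts (62.2 to 62.3). Gm42418 is a gene model that lies over ribosomal RNA sequence. These intervals cover counting error only.

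The first question was how the circadian clock ran in each tissue. Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, GRCm38 chromosome 7, 113207465 to 113314126), was at 38.4 ± 4.27 CPM at ZT0 (SD, n = 12) and 0.878 ± 0.259 CPM at ZT9 (SD, n = 11) in liver, a fitted peak-to-trough ratio of 31.8-fold (log2 4.99 ± 0.27, SE, n = 77). Group means are of counts scaled to the library total times the TMM factor. The ratio was 1.74-fold in cortex (log2 0.80 ± 0.05, n = 78), 1.89-fold in striatum (log2 0.92 ± 0.11, n = 60) and 1.35-fold in hypothalamus (log2 0.44 ± 0.03, n = 77). Dbp, a transcription factor driven by the clock (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), swung 132-fold in liver with a peak at ZT9.69, 2.77-fold in cortex, 2.18-fold in hypothalamus and 2.05-fold in striatum. Nr1d1, which encodes the repressor REV-ERB alpha, swung 79.8-fold in liver and 2.00-fold in cortex, and Npas2, a partner of BMAL1, 340-fold in liver and 1.34-fold in cortex. Per2, a repressor of the clock, swung 8.90-fold in liver with a peak at ZT15.6 and 3.01-fold in cortex with a peak at ZT17.4. Of the exonic bases of Dbp 18.0% are shared with Sphk2, and of those of Nr1d1 8.55% with Thra, so part of their counts is uncertain.

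Of the 24 genes on the list of core clock and clock output genes, 20 were called rhythmic in cortex, 17 in hypothalamus and 9 in striatum, and in liver 20 of 23 were called. Adjusted over the list alone, the counts were 20 in cortex, 20 in hypothalamus, 14 in striatum and 21 in liver. The genes called in striatum included Arntl, Dbp, Nr1d1 and Per2. The 37.5% of members called in striatum lay above the tissue's 5.70% (Fisher's exact test, one-sided, adjusted p = 4.09e-05). By the same test the share was above the tissue's in cortex (adjusted p = 0.000739) and hypothalamus (3.1e-05), and not in liver (0.350). It takes the members as independent. The median log2 peak-to-trough ratio over the list was 0.64 in cortex, 0.41 in striatum, 0.30 in hypothalamus and 3.15 in liver. Members that peak at different times can cancel in the mean of the list, so that mean is a weak test of the clock. The mean of the list cycled in cortex, hypothalamus and liver (permutation test, p = 1e-05 in each, the smallest that 100000 permutations can give; Benjamini-Hochberg adjusted p = 4.21e-05), and in striatum it did not pass (permutation test, p = 0.0970, adjusted p = 0.179). The test of the difference in rhythm between tissues called 20 of 23 clock genes between cortex and liver, 17 of 24 between cortex and hypothalamus, 21 of 23 between hypothalamus and liver, 20 of 23 between striatum and liver, 3 of 24 between cortex and striatum and 3 of 24 between striatum and hypothalamus. These fits had no mouse block. With it edgeR called 0 genes of any kind between striatum and hypothalamus (560 at an unadjusted p under 0.05) and 9 between cortex and striatum. Among the 17 clock genes called in both cortex and hypothalamus, the mean difference in peak time, hypothalamus minus cortex, was -3.17 h. It was the largest of the 6 pairs, and no spread was computed. Over all 3411 genes called in both tissues it was -0.333 h. For clock genes striatum minus cortex was -0.661 h, liver minus cortex -1.87 h and hypothalamus minus striatum -1.97 h. Liver minus striatum was -0.944 h and liver minus hypothalamus 1.30 h.

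**Figure D1:**
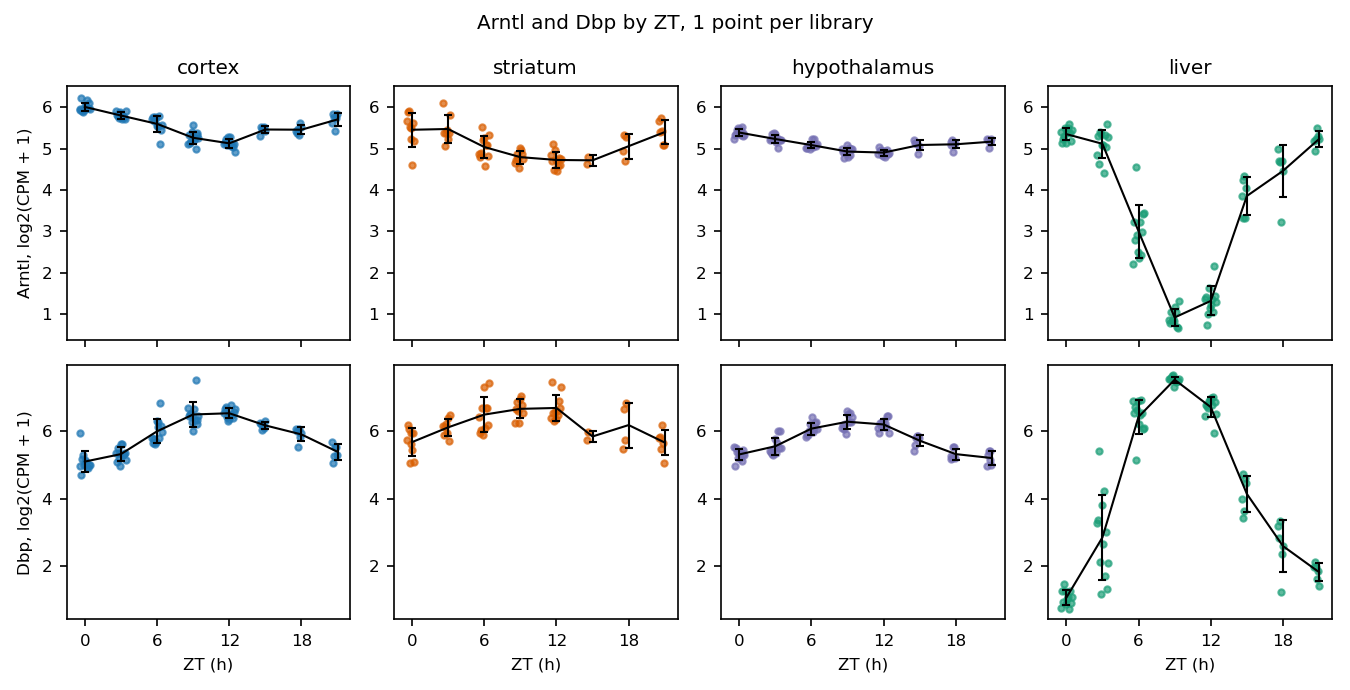
Expression of Arntl and Dbp in each tissue, as log2(CPM + 1), against ZT in hours, with a point for each library, a line through the group means and bars of 1 SD. CPM is scaled to the library total alone. The fitted ratio of Arntl is 31.8-fold in liver and between 1.35-fold and 1.89-fold in the brain tissues.

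In cortex, genes induced by neuronal activity cycled together. Arc, a regulator of glutamate receptor traffic at synapses (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), was at 342 ± 151 CPM at ZT15 (SD, n = 6) and 40.6 ± 9.93 CPM at ZT3 (SD, n = 12), and all 6 libraries at ZT15 lay above all 12 at ZT3. Its fitted ratio was 9.64-fold (log2 3.27 ± 0.31, SE, n = 78; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.2e-12). Of the 23 immediate early genes, which neurons switch on within minutes of stimulation, 22 were called rhythmic (22 adjusted over the list alone), among them the transcription factor genes Egr2 at 7.21-fold, Fos at 4.73-fold and Egr1 at 3.14-fold, and Homer1, a scaffold gene of the synapse, at 2.38-fold. The mean of that list had a log2 ratio of 1.14 ± 0.13 (SE, n = 78) and a peak at ZT19.7 (permutation p = 1e-05, adjusted p = 4.21e-05).

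Genes that respond to glucocorticoids, the adrenal stress hormones, peaked earlier in cortex, with 16 of 17 called (16 adjusted over the list alone) and a peak of the list mean at ZT15.5. The fat droplet gene Plin4 was at 10.5 ± 5.03 CPM at ZT15 (SD, n = 6) and 1.20 ± 0.195 CPM at ZT3 (SD, n = 12), a 9.28-fold ratio (log2 3.21 ± 0.20). Chaperone genes peaked at ZT21.6 with 17 of 20 called, genes of endoplasmic reticulum (ER) stress at ZT21.1 with 19 of 20, and genes of cholesterol synthesis at ZT8.26 with 16 of 22 (17, 19 and 17 adjusted over each list alone). Of the 3 RNA-binding genes induced by cold, Cirbp (log2 1.07 ± 0.06, peak at ZT8.78) and Rbm3 (log2 0.68 ± 0.05, peak at ZT16.6) were called (2 adjusted over the list alone), Srsf5 was not, and the list mean peaked at ZT11.7. Of the 12 endothelial and mural markers 10 were called (10 adjusted over the list alone), and Cldn5, a tight junction gene of the blood-brain barrier, ran from 30.8 ± 4.03 CPM at ZT0 (SD, n = 12) to 13.9 ± 2.30 CPM at ZT12 (SD, n = 12). The list means for fatty acid oxidation (log2 0.14 ± 0.03) and for liver genes under feeding and clock control (log2 0.18 ± 0.04) passed too. Those of oligodendrocytes and astrocytes passed narrowly (permutation test, adjusted p = 0.0494 and 0.0487), but not with the median over members (0.168 and 0.191), nor that of oligodendrocytes with the second cycle as a covariate (0.0885) and that of astrocytes with the first cycle alone (0.0897). Without ZT0 replicate 1 and ZT9 replicate 9 the astrocyte mean did not pass (adjusted p = 0.0692), and those of gluconeogenesis and glycogen (adjusted p = 0.0241) and of glutamate and GABA synapses (adjusted p = 0.0268) did.

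Across the cortex, 8545 of 19564 genes tested (43.7%) were called rhythmic, 1562 of them with a ratio of 1.5-fold or more and 363 with 2-fold or more. The flavin monooxygenase gene Fmo2, at 4.54-fold, Tnfrsf25, at 4.23-fold, and the clock output gene Ciart, at 4.19-fold, were among the 10 with the largest ratios. Ttr, the transthyretin gene of the choroid plexus, was also among them at log2 2.38 ± 0.79 with a peak at ZT20.1, and at log2 2.48 with a peak at ZT14.7 without the libraries ZT0 replicate 1 and ZT9 replicate 9. All 10 were still called without that pair of libraries.

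In striatum, the fat droplet gene Plin4 was at 21.5 ± 5.71 CPM at ZT15 (SD, n = 2) and 1.83 ± 0.880 CPM at ZT3 (SD, n = 8), a fitted 10.7-fold ratio (log2 3.42 ± 0.26, SE, n = 60). Hif3a, a member of the hypoxia-inducible factor family, swung 5.92-fold (log2 2.57 ± 0.22), the heat shock gene Hspa1b 4.99-fold (log2 2.32 ± 0.25) and Fmo2 3.82-fold (log2 1.93 ± 0.17). Of 20 chaperone genes 16 were called (17 adjusted over the list alone) with a peak of the list mean at ZT21.8, of 20 ER stress genes 11 (12), and of 18 glucocorticoid-responsive genes 10 (12) with a peak at ZT14.4. Of 23 immediate early genes 9 were called (13 adjusted over the list alone), and the list mean had a log2 ratio of 0.57 ± 0.16 and a peak at ZT20.8, but did not pass with the second cycle as a covariate (permutation test, adjusted p = 0.0529) or with the first cycle alone (adjusted p = 0.174). Means for cold-inducible genes, cholesterol synthesis, endothelial and mural markers and liver genes under feeding and clock control also passed. Of the 22 genes of cholesterol synthesis edgeR's quasi-likelihood test called 0 in striatum (0 adjusted over the list alone), with 3 at an unadjusted p under 0.05, and DESeq2 called 1. Without ZT21 replicate 3 and ZT3 replicate 5 the means for cholesterol synthesis and for feeding did not pass (permutation test, adjusted p = 0.0816 and 0.0671).

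The 10 striatum genes with the largest ratios were of another kind. Apart from Gm15564 they included Gabra6 (log2 14.54 ± 2.17), Pcp2, a Purkinje cell gene, Cbln3, a granule cell gene (log2 8.27 ± 1.02), Cnpy1, Car8 and Neurod1, genes strongly expressed in cerebellum. Of the exonic bases of Pcp2 51.5% are shared with Pet100, and 13% of those of Neurod1 with Cerkl and Gm26755. Cbln3 was at 268 ± 655 CPM at ZT21 (SD, n = 6), a mean carried by replicate 3, which held 1660 CPM (1646 to 1674) when scaled to its total alone. Without ZT21 replicate 3 and ZT3 replicate 5, 1 of the 10 was called, namely Il20rb, whose peak moved from ZT19.9 to ZT8.46 and whose log2 ratio went from 4.04 to 1.11. Cbln3 then had a log2 ratio of 0.20 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.893). Of 21637 genes tested, 1233 (5.70%) were called, 669 at 1.5-fold or more, and without these libraries 1232 and 589. A random reassignment of ZT to the striatum libraries called 4464 genes, so chance was not excluded for the striatum count.

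In hypothalamus, Plin4 was at 16.7 ± 8.42 CPM at ZT15 (SD, n = 6) and 2.32 ± 0.549 CPM at ZT6 (SD, n = 12), a 7.04-fold ratio (log2 2.82 ± 0.17, SE, n = 77). Hif3a swung 4.55-fold (log2 2.19 ± 0.16), the kinase gene Sgk1, a target of glucocorticoids, 3.98-fold (log2 1.99 ± 0.14) and Hspa1b 3.76-fold (log2 1.91 ± 0.22). Kirrel2, an adhesion gene (ENSMUSG00000036915, chromosome 7, 30447534 to 30457690), was at 4.93 ± 1.35 CPM at ZT15 (SD, n = 6) and 1.24 ± 0.186 CPM at ZT3 (SD, n = 12), and all 6 libraries at ZT15 lay above all 12 at ZT3 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.4e-27).

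Of 18 glucocorticoid-responsive genes 17 were called in hypothalamus (18 adjusted over the list alone) with a peak of the list mean at ZT14.8, of 20 chaperone genes 19 (20) with a peak at ZT21.0, of 20 ER stress genes 15 (17) and of 23 immediate early genes 12 (13). Means of cold-inducible genes, cholesterol synthesis, fatty acid oxidation and liver genes under feeding and clock control passed as well. With the first cycle alone those of immediate early genes, cholesterol synthesis and fatty acid oxidation did not (permutation test, adjusted p = 0.136, 0.136 and 0.474), nor did fatty acid oxidation with the median over members (adjusted p = 0.154). The hypothalamic neuropeptide list had 2 of 23 members called (1 adjusted over the list alone), and its mean did not pass (permutation p = 0.769, adjusted p = 0.830). They were Vip, a peptide of the suprachiasmatic nucleus (log2 0.73 ± 0.23, peak at ZT12.4), and Prok2 (log2 1.07 ± 0.20, peak at ZT4.51), named here after their values were seen. In all, 4967 of 20407 genes tested (24.3%) were called, 936 at 1.5-fold or more and 254 at 2-fold or more. The ratios of the pituitary hormone genes Gh (log2 12.69 ± 1.68) and Prl (log2 11.30 ± 1.59) rested on ZT0 replicate 9 and ZT9 replicate 9. Without them Gh was at log2 1.81 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.256) and Prl at log2 2.42 (adjusted p = 0.0337).

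In liver, metabolic genes cycled in large groups. Elovl3, an elongase of long-chain fatty acids (ENSMUSG00000038754, chromosome 19, 46131897 to 46135694), was at 913 ± 184 CPM at ZT0 (SD, n = 12) and 43.7 ± 10.5 CPM at ZT12 (SD, n = 12), a 17.6-fold ratio (log2 4.14 ± 0.15, SE, n = 77). Of 22 genes of cholesterol synthesis 21 were called (21 adjusted over the list alone) with a peak of the list mean at ZT0.316, and Hmgcs1, an early enzyme of that pathway, swung 3.72-fold (12.1% of its exonic bases are shared with Gm48342). Of 16 genes of fatty acid synthesis 15 were called (15) with a peak at ZT21.3, and of 16 genes of gluconeogenesis and glycogen 14 (14) with a peak at ZT14.1, among them Gys2, the liver glycogen synthase, at 4.39-fold (log2 2.13 ± 0.07). Of 19 genes of xenobiotic metabolism 13 were called (13) with a peak at ZT13.4, among them Cyp2a5 at 7.86-fold (log2 2.98 ± 0.11) and Por, the electron donor of cytochromes P450, at 5.27-fold (log2 2.40 ± 0.08).

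The 15 genes of bile acid synthesis and transport had 13 called (13 adjusted over the list alone), and Abcb11, the bile salt export pump, was at 875 ± 65.9 CPM at ZT3 (SD, n = 12) and 336 ± 39.4 CPM at ZT12 (SD, n = 12). All 18 glucocorticoid-responsive genes were called (18 adjusted over the list alone) with a peak of the list mean at ZT15.9, and the cochaperone gene Fkbp5 swung 5.61-fold. Of 20 chaperone genes 19 were called (19) with a peak at ZT19.1, and Hsph1 ran from 156 ± 44.0 CPM at ZT15 (SD, n = 6) to 19.9 ± 5.57 CPM at ZT6 (SD, n = 12). The cell cycle genes Cdkn1a, at 21.6-fold with a peak at ZT21.5, and Wee1, at 8.40-fold with a peak at ZT12.6, were among 13 of 15 called in their list (14 adjusted over the list alone), whose mean did not pass (permutation p = 0.198, adjusted p = 0.318). Pdk4, a brake on glucose oxidation, swung 11.2-fold, while the mean of the list for fatty acid oxidation that holds it did not pass (permutation p = 0.288, adjusted p = 0.423).

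Over the liver, 11769 of 16159 genes tested (72.8%) were called, 4504 at 1.5-fold or more and 1791 at 2-fold or more. Against that background the share of called members was above the tissue's share in 2 of the 29 lists tested by Fisher's exact test (one-sided, Benjamini-Hochberg), cholesterol synthesis (adjusted p = 0.0476) and glucocorticoid-responsive genes (adjusted p = 0.0247). The 10 genes with the largest ratios held the clock genes Npas2, Dbp, Nr1d1 and Ciart, and Rgs16, a regulator of G protein signalling (171-fold, peak at ZT9.98), which shares 10.1% of its exonic bases with Gm28513. They also held Gm26917, Gm23935, Gm24270, Mir6240 and Gm15564, whose ratios rested on ZT18 replicate 4. Gm26917 went from log2 6.34 to 0.73 without that library, and Gm23935 from 6.47 to 0.67.

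**Figure D2:**
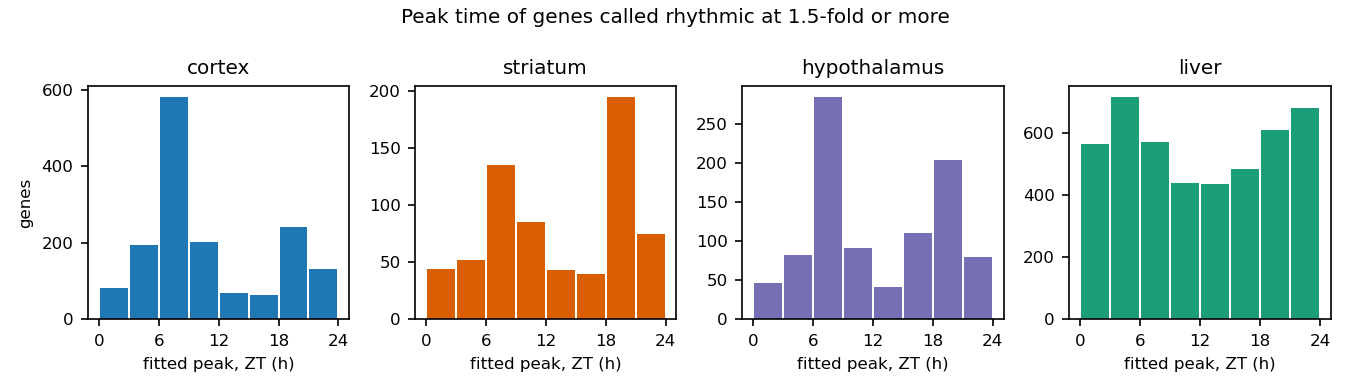
Number of genes called rhythmic with a ratio of 1.5-fold or more, in bins of 3 h of fitted peak time (ZT, hours), for each tissue. Between ZT6 and ZT9 lie 581 of 1562 genes in cortex and 284 of 936 in hypothalamus, and in liver each bin holds between 437 and 716 genes.

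The next question was which rhythms the tissues shared. Fmo2 swung 4.54-fold in cortex, 3.82-fold in striatum, 3.57-fold in hypothalamus and 3.8-fold in liver, with peaks from ZT14.3 to ZT15.0. Hif3a swung 2.95-fold or more in each tissue with peaks between ZT12.2 and ZT13.9, though in liver it was at 0.319 CPM at its highest. Hspa1b swung from 2.45-fold in cortex to 10.5-fold in liver, and Plin4 from 2.27-fold in liver to 10.7-fold in striatum. Foxs1, a forkhead transcription factor gene, swung 2.50-fold in cortex and 6.10-fold in liver. In all 4 tissues 609 genes were called among 14765 tested in each, against 75.7 if the lists were independent. Of the 14765, liver called 10841, so this excess says little about sharing with liver. Genes called in both tissues of a pair numbered 3411 against 2089 for cortex and hypothalamus and 1013 against 507 for cortex and striatum. For striatum and hypothalamus they numbered 944 against 290. In pairs with liver they lay nearer to independence, at 5438 against 4989 (cortex), 3012 against 2717 (hypothalamus) and 792 against 676 (striatum). Lists for chaperones, ER stress, glucocorticoid response and cold-inducible genes passed in all 4 tissues, in the main fit and under each other setting of the list means. Those for immediate early genes, cholesterol synthesis and feeding passed in all 4 in the main fit, but in striatum not with the second cycle as a covariate (permutation test, adjusted p = 0.0529, 0.144 and 0.0577), and the last 2 not without ZT21 replicate 3 and ZT3 replicate 5. With the first cycle alone all 3 lost the call in striatum, immediate early genes in hypothalamus and liver too (adjusted p = 0.136 and 0.255) and cholesterol synthesis in hypothalamus (adjusted p = 0.136). The test sets no peak time, and these 3 lists did not peak together in all tissues. In cortex, striatum, hypothalamus and liver the peaks were ZT19.7, ZT20.8, ZT20.4 and ZT14.1 for immediate early genes. They were ZT8.26, ZT9.22, ZT8.35 and ZT0.316 for cholesterol synthesis. For feeding they were ZT16.75, ZT9.15, ZT8.43 and ZT13.1. Lists for ribosomal proteins and oxidative phosphorylation passed in none. Without the liver library ZT18 replicate 4 these passed in liver (permutation test, adjusted p = 0.00138 for ribosomal proteins and 3.8e-05 for oxidative phosphorylation). List means passed in 12 of 31 tests in cortex, 8 of 31 in striatum, 9 of 31 in hypothalamus and 24 of 29 in liver. Zglp1 was also among the 10 shared genes with the largest minimum ratio, but 92.2% of its exonic bases lie in other genes. At an adjusted p of 0.01 the shared count was 329.

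Tissues were then compared in pairs by testing the difference in rhythm itself. The mitochondrial protease gene Clpx swung 6.58-fold in liver against a log2 ratio of 0.01 ± 0.03 in cortex, and Por and Lgalsl were with it among the genes with the smallest p in each pair with liver (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.0e-52 for Clpx between cortex and liver). Between cortex and hypothalamus Arc differed, with a log2 ratio of 3.27 ± 0.31 in cortex and 0.29 ± 0.07 in hypothalamus, as did Rtp1, a receptor transport gene that swung 6.33-fold in cortex and 1.20-fold in hypothalamus. Kirrel2 swung 3.98-fold in hypothalamus and 1.73-fold in cortex, and Mthfd1l, a gene of folate metabolism, 1.93-fold in cortex and 1.35-fold in hypothalamus.

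The rhythm differed in 9444 genes between cortex and liver, 9143 between hypothalamus and liver, 6400 between striatum and liver and 1168 between cortex and hypothalamus. With the mouse as a block, which paired the tissues of the same animal, these were 9226, 8745, 5269 and 1396. Between cortex and striatum 97 genes differed, and 9 with the mouse block, and between striatum and hypothalamus 59. With the mouse block edgeR's quasi-likelihood test called 0 between striatum and hypothalamus, with 560 at an unadjusted p under 0.05, and limma without the block called 0. The 4 genes with the smallest p were Cbln3, Mybpc3, Hes3 and Mybpc1 between cortex and striatum, and Cbln3, Car8, Cnpy1 and Dao between striatum and hypothalamus. Without the libraries that stood apart, the striatum library ZT21 replicate 3 among them, 12 genes differed between striatum and hypothalamus and 112 between cortex and striatum, where 50 of the 97 were among them, and of these named genes Mybpc3 between cortex and striatum was still called (adjusted p = 0.0164). Of the genes called in both tissues, 92.7% peaked within 3 h of each other in cortex and striatum (1013 genes), 95.7% in striatum and hypothalamus (944), 85.0% in cortex and hypothalamus (3411), 41.7% in cortex and liver (5438), 50.5% in striatum and liver (792) and 43.4% in hypothalamus and liver (3012). The share that chance would give was not computed. Peaks that bunch at some times raise it, so these shares alone do not measure how well the tissues match.

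The last comparison asked whether expression at the same ZT differed between the cycles. In cortex, Cdhr1, a cadherin-related gene, was at 4.01 ± 3.68 CPM in the first cycle and 9.51 ± 3.28 CPM in the second (SD, n = 30 in each), and 28 of the 30 second-cycle libraries lay above the first-cycle mean (log2 1.46; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.5e-06). Lmo3, a neuronal transcription cofactor gene, was at 118 ± 30.5 CPM and 169 ± 28.5 CPM, and Col10a1 at 0.125 ± 0.0830 CPM and 0.380 ± 0.184 CPM. Markers of striatal projection neurons moved with the cycle in cortex, with a list mean 0.87 ± 0.22 (log2, SE) higher in the second cycle (permutation p = 0.000150, adjusted p = 0.0183, n = 30 in each). In striatum the same list had a difference of -1.10 ± 0.36 that did not pass (permutation p = 0.00424, adjusted p = 0.101, n = 22 and 26). It was the 1 list of 122 tested that passed, in a test added after the gene counts had been seen.

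In cortex 1290 of 18909 genes differed between the cycles, 868 higher and 422 lower in the second, and 6 when marker lists and Gm42418 entered the model. With the replicate number as a block 259 differed. Without ZT0 replicate 1 and ZT9 replicate 9, 3073 differed. In striatum 579 of 19813 genes differed, 130 higher and 449 lower, among them 2310075C17Rik at 2.47 ± 2.44 CPM in the first cycle (SD, n = 22) and 0.856 ± 0.770 CPM in the second (SD, n = 26). That gene was taken by alphabetical order among genes tied at an adjusted p of 0.0441 (edgeR's quasi-likelihood test). Without the library ZT3 replicate 5 edgeR called 0, with 4225 genes at an unadjusted p under 0.05, and with the replicate block 0, with 3516. With all libraries 4543 genes had an unadjusted p under 0.05, and DESeq2 called 1631. In hypothalamus and liver edgeR called 0 genes, with 1179 and 1101 at an unadjusted p under 0.05, and DESeq2's likelihood ratio test called 0 in each, with 1078 and 1161.

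**Figure D3:**
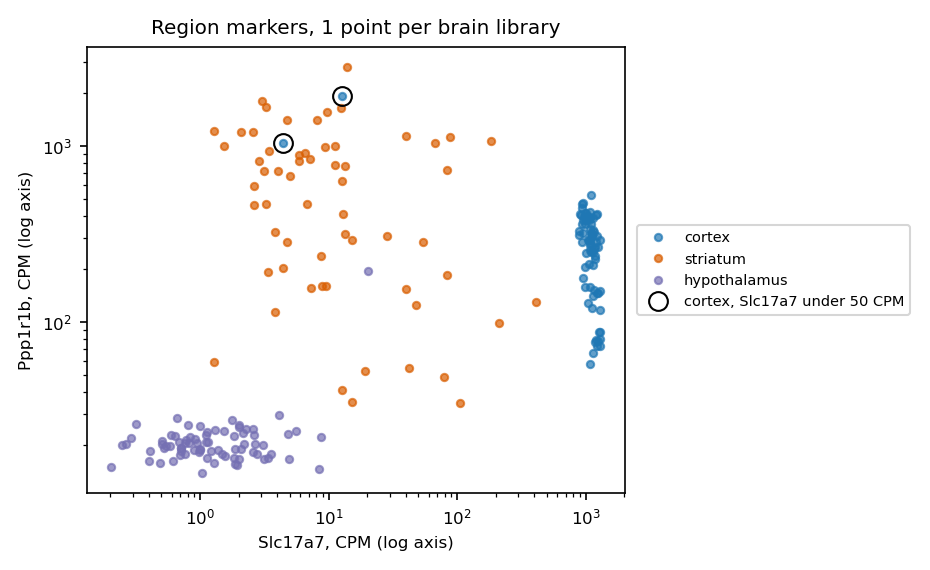
Slc17a7 against Ppp1r1b in CPM, on log axes, with a point for each cortex, striatum and hypothalamus library. The circled cortex libraries, ZT0 replicate 1 and ZT9 replicate 9, lie at 4.41 and 12.7 CPM of Slc17a7, away from the other 76 at 882 to 1300 CPM.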

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

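The tests of the cortex libraries without cortical markers, those with composition covariates, those with a replicate block between cycles and those without the libraries that stood apart were chosen only after the data had been seen, while the splits of the samples and the thinned cortex were planned before their results.

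Among groups of 4 to 10 libraries, 6 of 61 group values (depth, the Gm42418 share, Arntl and Dbp in each tissue, and Ppp1r1b in striatum) had a library beyond Dixon's limit, all in depth or the Gm42418 share, a rule that chance alone meets in about 1 in 20 groups. The striatum library ZT3 replicate 5 totalled 11.7 M counts, against 30.7 M for the next lowest of its group. The liver library ZT18 replicate 4 totalled 11.7 M, against 30.0 M, and held 62.3% of its counts in Gm42418, against 1.10% for the next. Gm42418 also took 16.9% in the striatum library ZT0 replicate 7, 10.8% in the striatum library ZT9 replicate 9 and 4.44% in the liver library ZT15 replicate 3, where the next held 6.01%, 5.54% and 1.59%.

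The cortex libraries ZT0 replicate 1 and ZT9 replicate 9 lacked cortical markers. Their Ppp1r1b, a gene of striatal projection neurons, was at 1036.5 CPM and 1930 CPM, against a median of 289 CPM and a highest value of 529 CPM in the other 76 cortex libraries. Low depth was argued against, since 2 of 2 totals (39.2 and 32.2 M) lay within the range of the others, 28.3 to 40.5 M. A swap with a striatum library was argued against too, since 0 of 60 striatum libraries held Slc17a7 at the cortical level, where the highest was at 410 CPM against 882 CPM for the lowest of the other cortex libraries. A candidate explanation that stayed open is that other brain tissue was taken or that the tube was exchanged with one outside the series. By the median of their pairwise r, 2 of 2 libraries correlated better with the striatum libraries (0.973 and 0.966) than with the other cortex libraries (0.961 and 0.95). These are Pearson r over 18983 genes, which are not independent. No biological explanation was tested.

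Fewer genes were called rhythmic in striatum (1233) than in cortex (8545). At a ratio of 2-fold or more the counts were 327 and 363, so the gap lay mostly in smaller ratios. The largest striatal ratios rested on the library ZT21 replicate 3, and chance was not excluded for the striatum count. Fewer libraries and thin ZT groups were argued against as the whole cause, since cortex thinned to the 60 libraries of the striatal layout gave 6163 to 7087 calls in 20 draws. Composition covariates raised the striatum count to 3296, which stayed below the lowest thinned cortex count by more than 1.5 times. So the part of composition that these covariates capture was argued against as the whole cause, though it may account for a part. They held no list of cerebellar or cortical markers, so composition of other kinds was not excluded. Of the smallest rhythms planted in simulated data 52.2% were found in cortex and 5.97% in striatum. So a lower power to find small rhythms in striatum stayed open. The direct test of the difference in rhythm called 97 genes between these tissues, and 9 with the mouse block. It found 10.4% of the smallest planted differences, so it cannot decide whether fewer genes cycle in striatum. A difference between the tissues stayed open too.

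The splits with ZT permuted excluded chance for the rhythm counts of cortex (8545, where the highest of the other splits called 22), hypothalamus (4967 against 123) and liver (11769 against 22), and at 1.5-fold for cortex (1562 against 21), hypothalamus (936 against 78) and liver (4504 against 21), with 1 of 25 splits, the real one, as large in each. In striatum 2 of 25 splits were as large, the other with 4464 calls against 1233 and 1850 against 669 at 1.5-fold. So chance was not excluded there, and a split with several times the real count points to a structure of the samples. The count in all 4 tissues was 609 against 0 in the highest other split (1 of 25). Since such splits leave few calls in cortex and liver (22 at most in each), this says little more than that the tissues have rhythms and does not test the sharing itself, and the count includes striatum calls for which chance was not excluded. With the cycle permuted within ZT groups, cortex gave 1290 against 0 and striatum 579 against 0 (1 of 25 each), which excluded chance for libraries exchanged freely within a ZT, but not a structure of the samples. With the replicate number as a block cortex gave 259, and with composition covariates 6. In striatum edgeR gave 0 with the block, 0 with these covariates, 0 without ZT3 replicate 5 and 0 without a filter, with 3516, 919, 4225 and 5934 genes at an unadjusted p under 0.05, while DESeq2 gave 1631 with all libraries. For hypothalamus (0 against 0) and liver (0 against 16) 25 of 25 splits were as large, since edgeR called 0 genes there, with 1179 and 1101 at an unadjusted p under 0.05, and DESeq2's likelihood ratio test 0, so the splits decide nothing there.

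The test of the difference in rhythm called 97 genes between cortex and striatum, 1168 between cortex and hypothalamus, 9444 between cortex and liver, 59 between striatum and hypothalamus, 6400 between striatum and liver and 9143 between hypothalamus and liver. With tissue names swapped within mice, limma called 1078 genes in the real data against 0 in the highest of the other 99 splits for cortex and hypothalamus, 8930 against 1540 for cortex and liver, 5327 against 462 for striatum and liver and 8610 against 577 for hypothalamus and liver, with 1 of 100 as large in each, which excluded chance. For cortex and striatum it called 7, and 2 of 100 splits were as large, the other with 299. That excluded chance by the share for the 7 genes, but a split with several times the real count points to a structure of the samples. The splits did not test the 97 genes that edgeR called, which were 9 with the mouse block. For striatum and hypothalamus limma called 0 against 1, with 100 of 100 as large, which a real count of 0 fixes beforehand. So the splits decide nothing about the 59 genes that edgeR called (1429 at an unadjusted p under 0.05).

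Between cortex and liver, edgeR's adjusted p was 1.3e-52 for Por, 4.0e-52 for Clpx and 1.3e-50 for Lgalsl. Between striatum and liver it was 5.2e-40 for Clpx, 6.3e-37 for Por and 8.6e-37 for Lgalsl. Between hypothalamus and liver it was 3.9e-51 for Clpx, 6.6e-51 for Por and 4.1e-49 for Lgalsl. Between cortex and hypothalamus it was 1.2e-17 for Rtp1, 1.0e-14 for Mthfd1l, 1.0e-14 for Kirrel2 and 5.9e-12 for Arc. Between cortex and striatum it was 2.3e-10 for Cbln3, 3.0e-10 for Mybpc3, 1.8e-09 for Hes3 and 3.0e-09 for Mybpc1, and between striatum and hypothalamus 5.3e-10 for Cbln3, 6.8e-08 for Car8, 3.4e-07 for Cnpy1 and 5.4e-07 for Dao. Without the libraries that stood apart, the striatum library ZT21 replicate 3 among them, the adjusted p of the genes in these last comparisons was 0.594 or more, except for Mybpc3 at 0.0164.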

How the results depend on the processing

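The tests without libraries that stood apart, with composition covariates and with a replicate block between cycles were chosen only after the results had been seen.

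Rhythm counts stayed within 1.5 times the main value under all 38 alternatives in cortex (7057 to 9507) and liver (9484 to 13338), under 37 of 38 in hypothalamus (2155 to 7136) and under 41 of 43 in striatum (326 to 3296). Leaving out a time point gave 7763 to 8842 in cortex, 828 to 1649 in striatum, 4303 to 5208 in hypothalamus and 11223 to 11917 in liver, and leaving out a replicate number 7492 to 8674, 946 to 1570, 4139 to 5326 and 11280 to 11983. Differences between tissues stayed within 1.5 times for cortex and hypothalamus (792 to 1512) and for the pairs with liver. Of 2444 values of named rhythms 2289 kept their call, 120 lost it and 34 gained it, and Il20rb in striatum reversed (log2 1.11 without ZT21 replicate 3 and ZT3 replicate 5). Of 144 values for pairs 124 kept it and of 42 for cycles 30. List means past the threshold numbered 53, and 45 to 54 under the alternatives. With the first cycle alone the calls lost included immediate early genes in striatum, hypothalamus and liver (permutation test, adjusted p = 0.174, 0.136 and 0.255), cholesterol synthesis in striatum and hypothalamus (0.311 and 0.136), endothelial and mural markers in striatum (0.0692), fatty acid oxidation in hypothalamus (0.474) and the urea cycle in liver (0.0888). With the median over members they included bile acids (0.406) and male-biased genes (0.0869) in liver.

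The cause of the following changes was not tested, except that the first cycle alone has fewer libraries and that a pseudocount shrinks ratios of low genes. At 1.5-fold, limma on FPKM with a pseudocount of 0.1 gave 839 in cortex, 443 in striatum and 448 in hypothalamus. With 1 it gave 176, 122, 84 and in liver 1687. No filter gave 2408 in cortex and 1510 in hypothalamus at 1.5-fold, 339 between cortex and striatum, 299 between striatum and hypothalamus. The first cycle alone gave 326 rhythms in striatum (255 at 1.5-fold) and 2155 in hypothalamus, and composition covariates 3296 in striatum. At an adjusted p of 0.01, 329 genes were shared by all tissues. Between cortex and striatum ZT as a factor gave 173. The replicate block gave 37 and the mouse block 9, and between striatum and hypothalamus they gave 3 and 0, and leaving out the libraries that stood apart gave 12. Between cycles in cortex leaving them out gave 3073, composition covariates 6 and the replicate block 259. In striatum the L code gave 1626 and DESeq2 1631, while edgeR gave 0 without a filter, 0 without ZT3 replicate 5, 0 with composition covariates and 0 with the replicate block, with 5934, 4225, 919 and 3516 genes at an unadjusted p under 0.05. In hypothalamus composition covariates gave 1 and the replicate block 1. Of the smallest rhythms planted in simulated striatum data 5.97% were found.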

Other observations

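The tests of clock time shared between tissues, of list means between cycles and without ZT18 replicate 4 were chosen only after the results had been seen, while those with the L code and depth removed were planned before their results.

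The liver list of interferon and acute phase genes had a mean that cycled, though its share of called members (61.1%) was not above that of the tissue (72.8%; Fisher's exact test, one-sided, p = 0.913). Usp18, which removes the ubiquitin-like protein ISG15, was at 8.41 ± 2.35 CPM at ZT6 (SD, n = 12) and 2.87 ± 0.922 CPM at ZT18 (SD, n = 6), a 2.61-fold ratio, and Ifit1 (log2 1.27 ± 0.14) and Isg15 (log2 1.11 ± 0.11) peaked at ZT4.99 and ZT5.00. Of the 18 genes of interferon and acute phase 11 were called in liver (11 adjusted over the list alone), with a log2 ratio of the list mean of 0.44 ± 0.11 (SE, n = 77) and a peak at ZT4.10 (permutation test, adjusted p = 0.00210). Markers of liver cells other than hepatocytes, among them the macrophage gene Cd5l (log2 0.91 ± 0.18), had 10 of 15 called (10 adjusted over the list alone) and a peak of the list mean at ZT1.66, and 8 of 11 microglial genes, which macrophages of the liver also express, had 8 adjusted over the list alone and a peak at ZT3.99. The hepatocyte list had 6 of 14 called (6 adjusted over the list alone) and its mean did not pass (permutation test, adjusted p = 0.506). Of the 10 male-biased liver genes 5 were called (5), with a peak at ZT0.715, and the steroid enzyme gene Hsd3b5 swung 2.15-fold. Genes of the urea cycle and amino acid breakdown had 13 of 15 called (15 adjusted over the list alone) and a peak at ZT12.7, and Asl, an enzyme of that cycle, had a log2 ratio of 1.09 ± 0.07. Of 13 liver genes under feeding and clock control 10 were called (10), and Upp2, a uridine phosphorylase, had a log2 ratio of 2.91 ± 0.13 and Nampt, of NAD synthesis, 2.05 ± 0.08. The blood list had 2 of 7 called in liver (2) and passed with all libraries (permutation test, adjusted p = 0.0424) but not without ZT18 replicate 4 (adjusted p = 0.0943).

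In cortex 8 of 12 choroid plexus genes were called (8 adjusted over the list alone) while the list mean did not pass (permutation test, adjusted p = 0.586), and of 7 oligodendrocyte precursor genes 3 were called (3) with an adjusted p of 0.165 for the mean. Among synaptic genes 2 of 20 were called in cortex (1 adjusted over the list alone), with an adjusted p of 0.720 for the mean. Of 8 pituitary genes measured in hypothalamus 2 were called (2), with an adjusted p of 0.441 for the mean. Adjusted p of the mean over ribosomal proteins was 0.271 in cortex, 0.912 in striatum, 0.823 in hypothalamus and 0.370 in liver, and over oxidative phosphorylation 0.397, 0.823, 0.905 and 0.114.

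The clock genes of a library were used to read its clock time, with the library left out of the reference, from 13 genes in cortex, 8 in striatum, 4 in hypothalamus and 19 in liver, so the tissues are not alike in precision. The time differed from the label by a median of 0.700 h in cortex, 1.12 h in striatum, 1.10 h in hypothalamus and 0.700 h in liver, and by over 3 h in 3, 4, 15 and 0 libraries. The farthest cortex libraries were ZT18 replicate 2 at -11.6 h and ZT21 replicate 4 at 8 h. The mouse of the former read 0.05 h in liver and 6.6 h in hypothalamus. That of the latter read -1.55 h in liver, 5.65 h in striatum and -4 h in hypothalamus. Neither cortex library was among those left out as standing apart. The deviation within a time point was compared between tissues of a mouse in 18 correlations, 6 pairs of tissues under 3 definitions, adjusted together. With all libraries Pearson r was 0.433 for cortex and striatum (permutation p = 0.00664, adjusted p = 0.0239, 59 mice), with Spearman rho 0.286 (permutation p = 0.0455, adjusted p = 0.0910), and r was 0.195 without the 2 farthest mice, so the relation rests on those samples. For cortex and liver r was 0.213 (permutation p = 0.0352, adjusted p = 0.0905, 77 mice), rho 0.428 (permutation p = 0.000160, adjusted p = 0.000960) and r without the 2 farthest 0.453. The other r were -0.265 for cortex and hypothalamus (rho -0.110), 0.121 for striatum and hypothalamus (rho 0.230), 0.108 for striatum and liver (rho 0.137) and 0.0917 for hypothalamus and liver (rho 0.195), with adjusted permutation p from 0.0679 to 0.574 for r and from 0.157 to 0.342 for rho. Another reading used 16 clock genes fixed for all tissues and, unlike the one above, kept each library in its own reference. With it r for cortex and liver was 0.344 (adjusted p = 0.00954), and 0.571 (adjusted p = 0.000180) among libraries within 6 h of their label. For cortex and hypothalamus these were 0.0577 (adjusted p = 0.779) and 0.397 (adjusted p = 0.0105; rho 0.415, adjusted p = 0.00270), against the negative r with all libraries, and for cortex and striatum 0.477 (adjusted p = 0.0239) and 0.321 (adjusted p = 0.118), so the relations depend on the definition. A candidate explanation is that animals differed in the phase of their clock. It was not tested, and the mice of the farthest cortex libraries had livers within 1.55 h of their label. For cortex and liver r was 0.278 with L code means removed and 0.184 with depth and the Gm42418 share removed. These lie between the 0.1 and 0.3 named in advance, but r was below 0.3 before any removal and rose with L code means removed, so that test could hardly have argued against either and decided nothing. With the fixed genes r was 0.317 and 0.332 after the same removals, and 0.503 and 0.570 near the label, all over 0.3, but libraries near the label are chosen by the measured time itself and no spread of these r was measured. For cortex and striatum r with L code means removed was 0.2795 with all libraries, 0.304 with the fixed genes and 0.0153 near the label. With depth and the Gm42418 share removed it was 0.429, 0.468 and 0.354. So the matter stayed open for both the L code and depth.

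No pair of libraries in a tissue was a copy of another: 0 pairs had identical counts, and the lowest chi-square per gene between a pair was 2.91 in cortex, 5.64 in striatum, 3.46 in hypothalamus and 11.5 in liver. In the brain tissues libraries with the same replicate number were correlated after group means were removed. The mean r over 2000 genes was 0.119 in cortex, 0.0906 in striatum, 0.214 in hypothalamus and 0.0101 in liver. For different numbers it was -0.000164, -0.00705, -0.0189 and 0.00312. Libraries of the same mouse code in different tissues had a mean r from -0.00158 (cortex and striatum) to 0.0354 (cortex and hypothalamus) after time point means were removed. The replicate block in the cycle test was added after the data had been seen, and in the other fits it was planned. Of 122 list differences between the cycles 20 had an unadjusted permutation p under 0.05 and 1 passed after adjustment, the striatal projection neuron list in cortex.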
